A study of Equus caballus with 31 samples.

How the data were processed

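RNA was sequenced from cells of synovial fluid and from blood mononuclear cells (PBMC) of horses with osteoarthritis (OA) and of healthy horses. Per the labels' protocols, fluid was treated with hyaluronidase and spun to a cell pellet, RNA came from frozen pellets, mRNA was taken with oligo(dT) beads and libraries were made with a TruSeq kit. Horses were classed by a lameness examination, radiographs and the response to joint analgesia. The labels give no batch, sex or age, so none of these entered a fit. A sequencing batch that follows disease is therefore not excluded in either tissue. In blood the OA libraries were also deeper. The 31 libraries form 4 groups: fluid OA (n = 5), fluid healthy (n = 11), PBMC OA (n = 6) and PBMC healthy (n = 9). The 23-cytokine immunoassay of the study was not used here.

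The deposited values are a signal per gene: read counts that the authors divided by a median-ratio size factor per library, with separate tables for fluid and blood. Partek, cutadapt, STAR 2.7.3, HTSeq and DESeq are named in the submitters' processing notes, with the horse build EquCab3.0; their settings are not given in the sources used here. The blood table pairs symbols with Ensembl identifiers, coordinates and a protein-coding class, whereas the fluid table has symbols only, so coordinates are those of the blood table. Transcripts outside the protein-coding class, and the mitochondrial genome were not analysed here. The tables held 17538 genes (fluid) and 17410 genes (blood), of which 16799 symbols were in both. No column was left unused.

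Every low value is a whole multiple of what 1 read is worth in its library, which gave back the reads and the depth. Between 99.85% and 99.98% of the values of a library came out whole within 0.1 of a read. Depth was 25.9 to 36.3 M reads in fluid and 23.9 to 34.8 M in blood, and precision is set mainly by the number of horses. No 2 libraries of a group were near copies of each other: the smallest chi-square per gene between libraries was 113 in fluid and 37.6 in blood.

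Within each tissue, log2(value + 1) of genes with a mean of at least 10 was fitted with limma 3.58.1 in R 4.3.3 (trend and robust variance), and OA was compared with healthy, two-sided, with Benjamini-Hochberg adjustment at 0.05. Adjusted p-values for genes are from this test unless another tool is named. Fold changes are on this log2 scale, which understates the change of low genes. Because the tables were normalized separately, no level was compared between tissues. The difference of the OA effect was fitted over all libraries with 4 group means and limma weights per tissue, on the 12733 genes with a mean of at least 10 in both tables; horses that gave both samples allowed a second fit on within-horse differences (the replicate block). The horse numbers in the titles pair the samples: in 13 of 13 horses the deviations of fluid and blood from their group means correlated at over 0.1 (0.123 to 0.391, median 0.252), and each fluid matched its own horse's blood best over 200 marker genes.

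Gene lists (35, for cell types, joint disease pathways, the cytokine panel and quality), the genes to be named, the tests and most alternatives were set before the data were examined. Lists with at least 3 tested genes entered limma's camera with a preset correlation of 0.01, adjusted over the lists. Camera asks whether a list's genes moved more than other genes. It was repeated with a correlation estimated per list, and fry asked whether a list moved on balance in 1 direction. An exact permutation test of each list's mean over every split of the libraries (4368 in fluid, 5005 in blood, 1287 of horses for within-horse differences; two-sided, adjusted over the lists) was added after random splits were seen to call many lists. Tests of lists in the difference between tissues were added after the gene fit was seen. The named genes per tissue were the 8 largest rises and 8 largest falls with an adjusted p below 0.05, a gene symbol and a mean of at least 50 in the higher group; up to 4 genes of smallest p from each list called or with at least 3 genes past the threshold; and the 4 cytokine panel genes of smallest p. After all fits 3 of these genes were taken out without being replaced and are not reported here singly, while the tests and lists kept them. For the difference between tissues they were the 5 largest and 5 smallest differences, and for a cell type not called the 2 genes of highest mean.

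The steps were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. The fluid comparison recovered 12% and 78% of them among 13851 genes, with 4 false calls. Blood recovered 79% and 99% among 13053 genes, with 12 false calls. The difference between tissues recovered 6% and 61% among 12670 genes, with 4 false calls, and the replicate block 0% and 23% with 0 false calls. In these simulations, where few genes changed, small changes in fluid and in the difference were mostly below detection. The real fits called many more genes, in fluid also many that changed less than 2-fold, so these rates do not carry over to them.

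Alternatives were pseudocounts of 0.5 and 5, no filter or a mean of at least 50, upper-quartile scaling, equal library totals, weights per library, a fit without the robust step, each library left out in turn (each horse for the difference between tissues), and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. On those reads edgeR called 1964 genes higher and 2043 lower in fluid, and 504 higher and 301 lower in blood. Added after seeing the data were fits without libraries that stand apart, reads thinned to equal totals, and the T cell list (fluid) or the monocyte list (blood) as a covariate. Genes of near-identical families, such as ribosomal proteins and MHC genes, are uncertain because the counting could split their reads; 2 Ensembl identifiers share the symbol CD14, whose value is uncertain for the same reason. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.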

Results

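Gene expression was measured by RNA sequencing in the cells of joint (synovial) fluid and in blood mononuclear cells (PBMC) of horses with naturally occurring osteoarthritis (OA) and of healthy horses. Fluid came from 5 OA and 11 healthy horses and PBMC from 6 OA and 9 healthy horses, each library from a separate animal within its tissue. Horses carry the names of the labels, OA_ for OA and ORC_ for healthy, with a number. For 13 horses, 5 with OA and 8 healthy, both samples were sequenced. Fluid libraries held 29.6 ± 3.51 M reads in OA (SD, n = 5) and 31.7 ± 3.27 M reads in healthy horses (SD, n = 11; two-sided exact permutation p = 0.25). PBMC libraries were deeper in OA, with 33.5 ± 1.14 M reads (SD, n = 6) against 27.5 ± 2.31 M reads (SD, n = 9; two-sided exact permutation p = 4e-04). Values below are median-ratio normalized read counts as mean ± SD, and fold changes are OA against healthy on the log2(value + 1) scale with their SE.

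The comparison of fluid asked how cells of the OA joint differ from those of the healthy joint. Many T cell, cytotoxic, interferon and MHC class I presentation genes fell in OA fluid, and many glycolytic and ribosomal and some matrix genes rose. CD2, a surface protein of T cells, fell from 11500 ± 4184 (n = 11) to 2859 ± 1285 (n = 5), a log2 change of -2.04 (SE 0.32, limma adjusted p = 0.00076). BNIP3, a hypoxia-induced gene of mitochondrial turnover, rose from 732.2 ± 128.6 to 2255 ± 629.6, a change of 1.60 (SE 0.18, adjusted p = 0.000442). Of 13885 genes tested, 2006 were higher and 1893 lower in OA; 1206 and 973 of these changed at least 2-fold.

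Of 15 T cell markers, 14 fell (15 adjusted over the list alone), with a median change of -2.04. Beside CD2 these included the receptor chains CD3D (-2.22) and CD247 (-2.37) and the receptor kinase ZAP70 (-2.35). The list had an adjusted p = 0.241 with an estimated correlation and an adjusted p of 0.00252 by exact permutation. Of 15 cytotoxic and NK cell genes, 14 fell (14 adjusted over the list alone; median -1.95), led by the transcription factor TBX21, from 4274 to 635.7, the death ligand FASLG (-2.68), CTSW (-2.34) and CD8A (-1.77). This list had an adjusted p = 0.241 with an estimated correlation and 0.00189 by exact permutation. Of 20 genes of T cell receptor signalling and memory, 10 fell (10 adjusted over the list alone; median -1.01), among them the kinase PRKCQ (-2.06), CD27 (-2.18) and BATF (-1.94). Its adjusted p = 0.241 with an estimated correlation and 0.00189 by exact permutation. In the list of regulatory and helper T cells, 8 of 14 genes fell and 1 rose (9 and 1 adjusted over the list alone; median -1.08). GATA3 (-2.51), CD40LG (-1.77), ICOS (-1.83) and IKZF2 (-1.61) were lower and CCR6, the gene that rose, was higher by 2.02. The adjusted p = 0.346 with an estimated correlation and 0.0192 by exact permutation. Of 14 checkpoint and tolerance genes, 7 fell (8 adjusted over the list alone; median -1.54), including the inhibitory receptors LAG3 (-1.59), PDCD1 (-1.56) and BTLA (-2.10) and the ligand CD274 (-1.52). For these genes the adjusted p = 0.203 with an estimated correlation and 0.00189 by exact permutation. The T cell list mean lay at 10.9 in healthy horse ORC_202, within the OA range of 8.76 to 10.9, and between 11.2 and 12.7 in the other healthy horses.

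Type I interferon response genes fell in 16 of 28 cases (19 adjusted over the list alone; median -1.08). XAF1 fell from 1428 to 312.1 (-2.12, SE 0.27, adjusted p = 0.0005), and IRF9, a subunit of the factor that drives interferon-stimulated genes, from 5950 ± 1103 to 2268 ± 920.1. DTX3L changed by -1.69 and USP18, a brake on interferon receptor signalling, by -2.17. The list had an adjusted p = 0.241 with an estimated correlation and 0.00252 by exact permutation. Of 14 genes of MHC class I presentation, 8 fell (9 lower and 1 higher adjusted over the list alone; median -0.69). The peptide transporter TAP1 fell from 12240 to 3350, TAP2 changed by -1.41, the MHC class I transactivator NLRC5 by -2.07 and TAPBP by -0.89. For this list the adjusted p = 0.419 with an estimated correlation and 0.00863 by exact permutation.

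Glycolysis and hypoxia genes rose in 15 of 24 cases (19 adjusted over the list alone; median 0.87). NDRG1, a hypoxia-responsive gene, rose from 767.2 to 5186 (2.75, SE 0.40), and the glycolytic enzymes PKM and ENO1 by 1.18 and 1.19. The list had an adjusted p = 0.241 with an estimated correlation and 0.00189 by exact permutation. Ribosomal proteins and immediate early and heat shock genes had been set as lists for sample quality. Both lists were higher in OA fluid, and whether sample quality or handling caused this was not tested. Of 65 ribosomal protein genes, 37 rose (54 adjusted over the list alone; median 0.79), with RPL22L1 at 1.55, RPL7 at 1.14, RPL26 at 1.13 and RPS3A at 1.10, and the adjusted p = 0.513 with an estimated correlation and 0.0256 by exact permutation. Of 26 genes of oxidative phosphorylation, 11 rose (13 adjusted over the list alone; median 0.50), among them UQCRC2 (0.73), COX7B (1.13), NDUFA8 (0.85) and ATP5MC1 (0.81). This list had an adjusted p = 0.513 with an estimated correlation and 0.0192 by exact permutation. Of 24 immediate early and heat shock genes, 9 rose (11 adjusted over the list alone; median 0.90). The nuclear receptor NR4A3 rose from 540.1 to 9520 (3.89, SE 0.86), the AP-1 member FOSL1 by 3.26 and the chaperones HSPD1 and HSPB1 by 1.0 and 1.25. Healthy horse ORC_202 had a mean of 13.19 for this list, above the OA range of 12.16 to 13.15, and the adjusted p = 0.346 with an estimated correlation and 0.0168 by exact permutation.

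**Figure D1:**
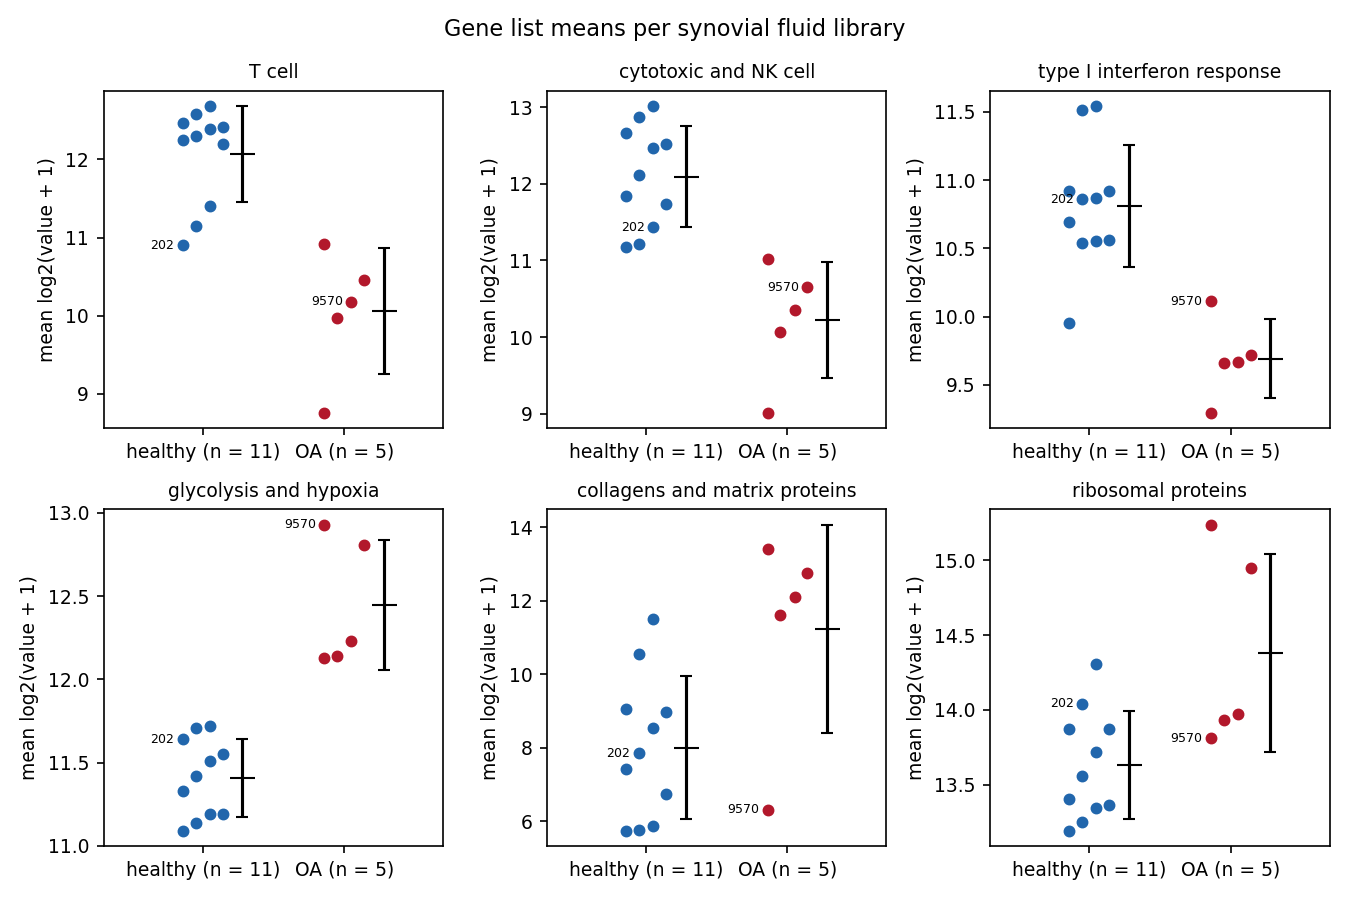
Mean log2(value + 1) of 6 gene lists (vertical axes, starting above 0) in each synovial fluid library of healthy (n = 11) and OA (n = 5) horses; points are libraries and bars the group mean ± SD. T cell means lay between 8.76 and 10.9 in OA, and for collagens and matrix proteins horse OA_9570 (6.31) lay apart from the other OA horses (11.6 to 13.4).

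Of 25 collagen and matrix protein genes limma called 10 higher (20 adjusted over the list alone, median 3.23), while edgeR called 17 and DESeq2 19, counted in either direction. Fibronectin, FN1, rose from 14660 ± 20880 (n = 11) to 163400 ± 107500 (n = 5), a change of 4.06 (SE 0.89, adjusted p = 0.00499). SPARC changed by 3.09, THBS1 by 2.71 and the proteoglycan VCAN by 3.04. The list mean was 6.31 in horse OA_9570, 11.6 to 13.4 in the other OA fluids and 5.73 to 11.5 in healthy fluids (11.5 in ORC_188 and 10.5 in ORC_205), and its adjusted p = 0.513 with an estimated correlation and 0.0443 by exact permutation. In the synovial fibroblast list limma called 4 of 19 genes higher (15 adjusted over the list alone, median 3.33), while edgeR called 12 and DESeq2 14, again in either direction. The limma calls were COL6A3 (4.39), COL5A1 (3.92), PDPN (3.81) and the hyaluronan synthase HAS1 (2.85). Each lost its call without horse OA_2615 (adjusted p = 0.0801, 0.1, 0.115 and 0.124) and without OA_3850 or OA_9350. COL5A1, PDPN and HAS1 also lost it without OA_1038 (0.0673, 0.0768 and 0.0689), and PDPN and HAS1 without some single healthy horses. This list mean was 5.27 in horse OA_9570, 11.1 to 13 in the other OA fluids and 5.07 to 10.7 in healthy fluids, with an adjusted p = 0.565 with an estimated correlation and 0.0509 by exact permutation. Of 21 matrix-degrading enzymes, 5 rose (5 adjusted over the list alone; median 1.90), including the serine protease HTRA1 (3.38), the aggrecanase ADAMTS4 (3.71, from 8.87 to 65.51), MMP19 (3.06) and ADAM9 (1.78). Its mean was 7.98 in horse OA_9570, 10.1 to 11.6 in the other OA fluids and 6.92 to 10.3 in healthy fluids, with ORC_188 (10.3) inside the OA range. The adjusted p = 0.513 with an estimated correlation and 0.0214 by exact permutation. Of 10 protease inhibitors, 3 rose (3 adjusted over the list alone; median 0.95), among them TIMP1, from 3355 to 13420, and TIMP2 (1.17). For inhibitors the adjusted p = 0.498 with an estimated correlation and 0.0123 by exact permutation.

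Of 22 genes of lipid handling and the lysosome, 5 rose (8 adjusted over the list alone; median 0.95), among them CHI3L1 (5.13, SE 1.35), CD9 (1.37), the fatty acid receptor CD36 (1.99) and PPARG (1.07). The list had an adjusted p = 0.586 with an estimated correlation and 0.0449 by exact permutation, and its camera call was lost without horse OA_2615 (adjusted p = 0.0924). Of 12 markers of tissue-resident macrophages only CD163, a haemoglobin scavenger receptor, rose, from 6251 to 36970 (1 adjusted over the list alone; list median 1.18). That list had an adjusted p = 0.586 with an estimated correlation and 0.142 by exact permutation, and lost its camera call without horse OA_2615 (adjusted p = 0.0876), OA_9350 (0.124) or OA_9570 (0.0542) or healthy horse ORC_196 (0.0515).

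Among called genes with a symbol and a mean of at least 50 in the higher group, the largest rise in fluid was EREG, encoding the growth factor epiregulin (EquCab3.0 chromosome 3, 63220455 to 63236724), from 5.463 ± 16.11 to 376.9 ± 418.6 (log2 change 7.09, SE 0.98, adjusted p = 0.0005). Its neighbour AREG, encoding amphiregulin, also a ligand of the EGF receptor (chromosome 3, 63151227 to 63161785), rose from 40.08 ± 108.2 to 1947 ± 2380 (6.98, SE 1.36). Healthy horse ORC_202 had the highest healthy values of both, 53.77 for EREG and 364.1 for AREG. VAT1L (chromosome 3, 26851591 to 26998352) changed by 6.60 and the transcription factor SIX2 (chromosome 15, 54766548 to 54769748) by 6.40. SPHKAP (6.13), the defensin DEFB1 (6.09) and SEC16B (5.89) were also among the largest rises. MAP7, a microtubule-associated protein (chromosome 10, 83075829 to 83225025), had the largest fall within the same limits, from 89.5 to 9.775 (-4.49, SE 0.74, adjusted p = 0.000944). MCHR1 (-4.46), SLC4A11 (-4.42), CCNP (-4.30), MAP6 (-4.05), FOXN1 (-4.01), FAM83F (-3.99) and LRATD2 (-3.84) followed.

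Among 17 tested genes of the cytokine panel, 3 rose and 4 fell (5 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 1). CXCL8, a neutrophil attractant, changed by 4.34 (SE 0.96; 2048 ± 5601 to 9449 ± 5783) and IL18 by 1.87, whereas CSF3 fell from 174 to 31.33 and CCL5 from 28100 to 7264. CXCL1 rose and CSF2 and TNF fell, and these 3 were named after their values were seen. The call of CXCL8 ended with edgeR (adjusted p = 0.127) and with DESeq2 (adjusted p = 0.11). Of the NF-kappa-B and inflammatory response list 4 genes rose and 2 fell (camera adjusted p = 0.431, 0.823 with an estimated correlation, exact permutation 0.0449). TNFAIP6, a hyaluronan-binding protein, rose from 121.8 to 3250 and PLAUR by 2.94, and BIRC3 (-1.10) and the NF-kappa-B inhibitor TNFAIP3 (-1.41) fell. Of the other chemokines and receptors 2 rose and 2 fell (camera adjusted p = 0.677): CXCL6 (4.35), CCR6 (2.02), CXCR3 (-1.87) and CCL22 (-2.86). Not called by camera were the lists of neutrophils (adjusted p = 0.0692), monocytes (0.178), B cells (0.246), endothelial cells (0.441), complement (0.431), proliferation (0.473), dendritic cells (0.515), platelets (0.823), mast cells and basophils (0.823) and MHC class II presentation (0.928). Erythroid markers had too few tested genes in fluid, and the mitochondrial genome was not analysed here.

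With camera, 17 of 33 lists were called in fluid, and 0 with an estimated correlation (6 at an unadjusted p under 0.05). Fry called 16 and exact permutation 18. The number of genes higher was 1208 without horse OA_2615, 1288 without horse OA_3850, 2805 without horse OA_9570 and healthy horse ORC_202 together, and 3654 with weights per library (2981 lower). Scaling to equal totals gave 1302 higher and 2766 lower, so that 32% of called genes were higher, against 51.4% in the main comparison, and moved the median of all genes from 0.08 to -0.12. All 17 called lists kept their direction under each scaling. Of 99 called genes of the lists and the largest changes, 77 stayed called whichever library was left out, and none changed direction in those fits. Beside the fibroblast genes, FOXN1, FAM83F, MAP6, MZB1, HAPLN1, COMP, TNFAIP3, CD163, ADAM9, CD9, CD36, CCL22, IL18, TIMP2, PPARG, TGFB2, TGFBI and VCAN lost their calls in some, at adjusted p of up to 0.184 (COMP without OA_3850). With the T cell list mean as a covariate, a fit chosen after the data were seen, 13 genes of those followed changed direction, among them PDCD1, CCL5, ADAM9 and HAS1, and 4 lists turned: lipid handling was called lower (median -0.71, camera adjusted p = 0.00632), and matrix-degrading enzymes (-0.27, 0.205), protease inhibitors (-0.29, 0.514) and resident macrophages (-0.79, 0.0603) were not called. With edgeR, SLC4A11, LRATD2, CCNP, MAP6, FOXN1, ADAMTS4, CCL22, TIMP2, PPARG and HAS1 also lost their calls.

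The comparison of PBMC asked whether the same disease is seen in circulating cells. Many proliferation genes fell in OA blood, and some monocyte markers rose. UBE2C, which acts in mitotic exit, fell from 415.7 ± 209.6 (n = 9) to 138.6 (n = 6), a log2 change of -1.52 (SE 0.33, limma adjusted p = 0.0221). VCAN, also a monocyte marker, rose from 11760 ± 3445 to 32770, a change of 1.43 (SE 0.25, adjusted p = 0.0135). Of 13072 genes tested, 418 were higher and 288 lower in OA, 170 and 105 of them at least 2-fold.

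Of 20 proliferation genes, 11 fell (18 adjusted over the list alone; median -0.98), among them the replication genes MCM2 (-0.70), TYMS (-0.82) and RRM2 (-1.22). The list had an adjusted p = 0.298 with an estimated correlation and 0.034 by exact permutation. Of 8 monocyte markers, 3 rose (8 adjusted over the list alone; median 1.01), among them VCAN and the chemokine receptor CCR2 (1.17). CD14 was higher by 1.61 (adjusted p = 0.0539). The monocyte list had an adjusted p = 0.271 with an estimated correlation and 0.00679 by exact permutation. Its mean was 13.3 to 13.4 in horses OA_3850, OA_9350 and OA_9570, 12.2 to 12.6 in the other OA horses, 11.7 to 12.1 in 8 healthy horses and 11 in healthy horse ORC_209. Proliferation means were lowest in horses OA_3850 (8.01) and OA_9350 (7.79), and healthy horse ORC_202 (8.42) lay below horses OA_1038, OA_2615, OA_4110 and OA_9570. Of 10 neutrophil markers S100A12 rose, by 1.40 (6 adjusted over the list alone; median 1.19), with an adjusted p = 0.342 with an estimated correlation and 0.0468 by exact permutation. Of 10 tissue-resident macrophage markers MERTK rose, by 1.13 (2 adjusted over the list alone; median 1.13), and the adjusted p = 0.298 with an estimated correlation and 0.015 by exact permutation.

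B cell markers had a median change of -0.81, and 1 of 11, the kinase BLK (-1.09), fell (5 adjusted over the list alone). For B cells the adjusted p = 0.342 with an estimated correlation and 0.0503 by exact permutation. Of 10 plasma cell markers, 3 fell (6 adjusted over the list alone; median -0.79): JCHAIN, the joining chain of IgA and IgM, from 16530 to 5329, FKBP11 (-1.16) and POU2AF1 (-0.86). That list had an adjusted p = 0.463 with an estimated correlation and 0.0726 by exact permutation. Of 20 genes of T cell receptor signalling and memory, 3 fell (7 adjusted over the list alone; median -0.22): CCR7, which guides cells to lymph nodes (-1.15), S1PR1 (-0.51) and TNFRSF4 (-0.56). Its adjusted p = 0.298 with an estimated correlation and 0.0468 by exact permutation. Of 15 T cell genes limma called 0 (4 at an unadjusted p under 0.05; edgeR called 0 and DESeq2 1; 1 adjusted over the list alone; median -0.19). The list was called lower by camera, with UBASH3A at -0.56 (adjusted p = 0.0551), and had an adjusted p = 0.614 with an estimated correlation and 0.375 by exact permutation. In the interferon list 1 of 28 genes fell, USP18 by 0.95 (3 adjusted over the list alone; median -0.37), and the adjusted p = 0.607 with an estimated correlation and 0.341 by exact permutation.

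**Figure D2:**
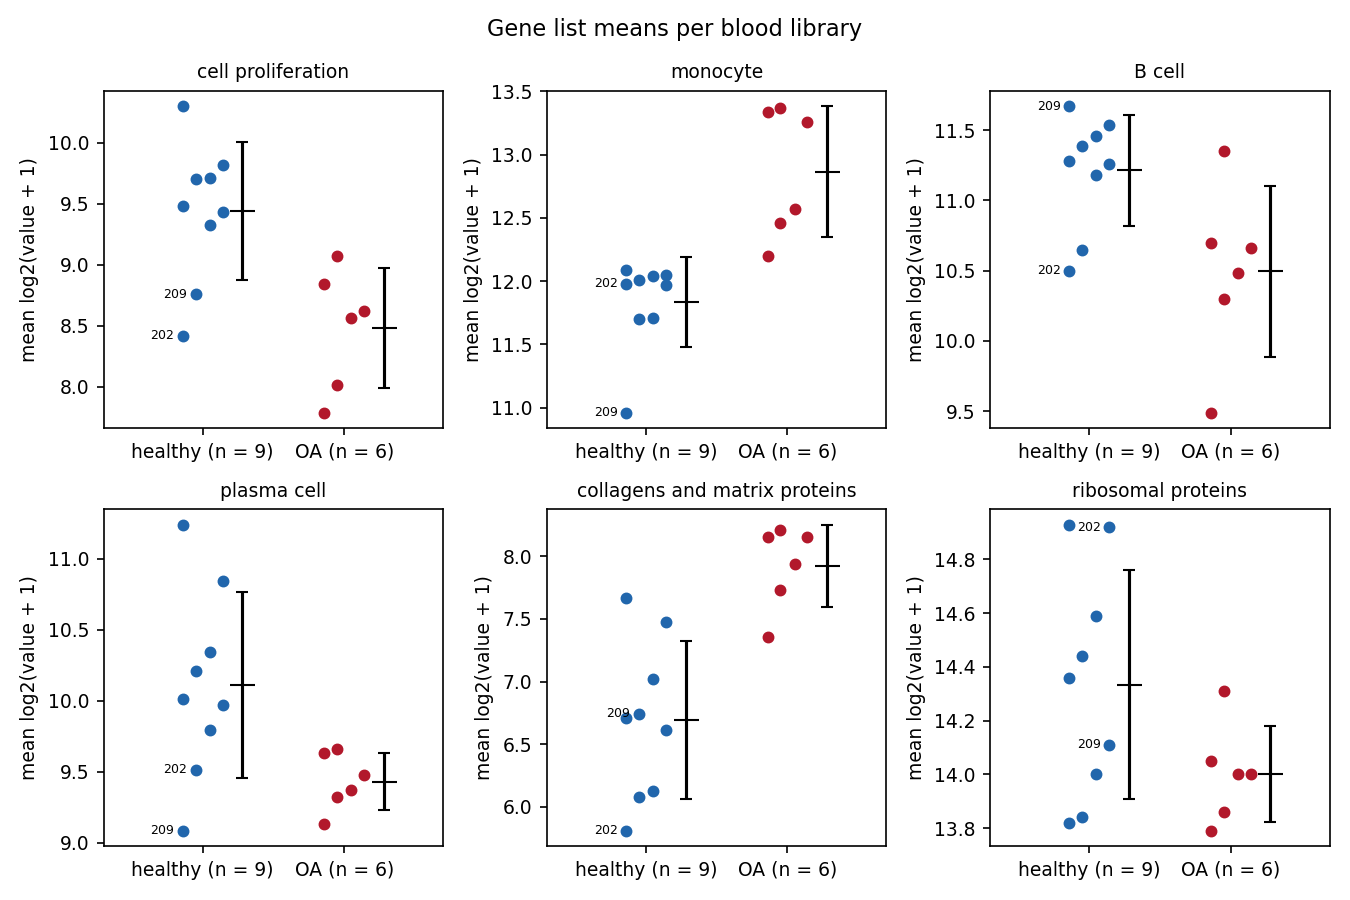
Mean log2(value + 1) of 6 gene lists (vertical axes, starting above 0) in each blood library of healthy (n = 9) and OA (n = 6) horses; points are libraries and bars the group mean ± SD. Monocyte means were 12.2 to 13.4 in OA and 11 to 12.1 in healthy horses, with healthy horse ORC_209 lowest, and healthy horse ORC_202 had the lowest healthy mean for proliferation (8.42) and B cells (10.5).

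FN1 was, within those limits, the largest rise in blood (EquCab3.0 chromosome 6, 5257446 to 5322595), from 1105 ± 1419 (n = 9) to 7904 ± 6908 (n = 6), a change of 3.73 (SE 1.0, adjusted p = 0.0424). With THBS1 (1.94) and VCAN it made 3 of 11 collagen and matrix genes that rose (4 adjusted over the list alone; median 1.29), a list with an adjusted p = 0.271 with an estimated correlation and 0.0136 by exact permutation. Of 12 matrix-degrading enzymes the proteases ADAM9 (0.80) and CTSB (0.78) rose (8 adjusted over the list alone; median 0.64), with an adjusted p = 0.271 with an estimated correlation and 0.0136 by exact permutation. Of 8 protease inhibitors limma called 0 over all genes (5 at an unadjusted p under 0.05; edgeR called 0 and DESeq2 2; 4 adjusted over the list alone; median 0.50), with SERPINB1 at 0.46 (adjusted p = 0.0688), and the list had an adjusted p = 0.271 with an estimated correlation and 0.0136 by exact permutation. In the NF-kappa-B list 3 of 23 genes rose (4 adjusted over the list alone; median 0.28): PLAUR (1.47), the co-receptor IL1RAP (1.27) and the inflammasome sensor NLRP3 (0.95). Its adjusted p = 0.298 with an estimated correlation and 0.0468 by exact permutation. LAMP2 (0.57) was the gene of 20 in lipid handling that rose (4 higher and 2 lower adjusted over the list alone; median 0.40), with an adjusted p = 0.298 with an estimated correlation and 0.0504 by exact permutation. Of 6 erythroid genes limma called 0 (3 at an unadjusted p under 0.05; edgeR called 0 and DESeq2 2; 3 adjusted over the list alone; median 1.69), and SLC4A1 was at 2.65 (adjusted p = 0.0909). The erythroid list had an adjusted p = 0.357 with an estimated correlation and 0.0504 by exact permutation. Of 65 ribosomal protein genes limma called 0 (15 at an unadjusted p under 0.05; edgeR called 0 and DESeq2 7; 0 adjusted over the list alone; median -0.36), and the list had an adjusted p = 0.596 with an estimated correlation and 0.208 by exact permutation. Of 26 genes of oxidative phosphorylation limma called 0 (0 at an unadjusted p under 0.05; edgeR and DESeq2 called 0; 0 adjusted over the list alone; median -0.20), and the list had an adjusted p = 0.614 with an estimated correlation and 0.375 by exact permutation.

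TMEM117 (chromosome 6, 63231901 to 63662997) rose from 11 ± 6.017 to 59.68 ± 19.87 (2.41, SE 0.34, adjusted p = 0.0116), and EPS8, a substrate of the EGF receptor, by 1.93 (SE 0.30). SALL3 (2.77), PLCB1 (1.91), SNAP91 (1.88) and KCNK4 (1.86) were the remaining largest rises within those limits, and SALL3 was at 0 in healthy horse ORC_202. LRFN1 (chromosome 10, 10312126 to 10319247) fell from 87.94 ± 31.76 to 19.18 ± 7.327 (-2.17, SE 0.32, adjusted p = 0.0116). The other largest falls were FGF19 (-2.76), GFRA1 (-2.67), KRT24 (-2.53), DEGS2 (-2.19), AIRE (-1.88), IGF2BP3 (-1.85) and PRDX2 (-1.65). The receptor PDCD1 fell from 507.7 ± 41.96 to 317.9 ± 53.69 (-0.69, SE 0.12, adjusted p = 0.012).

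Of 14 tested genes of the cytokine panel limma called 0 in blood (1 at an unadjusted p under 0.05; edgeR and DESeq2 called 0), and the panel was not called (camera adjusted p = 0.599). IL18 was at 0.90 (adjusted p = 0.131), IL1B at 1.0 (0.262), IL4 at -0.47 (0.489) and CCL5 at 0.33 (0.57). Camera also left uncalled the lists of endothelial cells (adjusted p = 0.182), immediate early and heat shock genes (0.193), complement (0.195), MHC class I presentation (0.224), cytotoxic and NK cells (0.225), other chemokines (0.292; CCR2 higher, CCR7 and CCR6 lower), regulatory and helper T cells (0.306) and chondrocytes (0.306). Platelets, MHC class II presentation and dendritic cells had an adjusted p of 0.454, synovial fibroblasts 0.679 and mast cells and basophils 0.871.

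In blood 17 of 34 lists were called by camera, 0 with an estimated correlation (4 at an unadjusted p under 0.05), 10 by fry and 9 by exact permutation. The gene counts rested on single horses: 16 higher and 17 lower without horse OA_3850, 17 and 18 without OA_9350, 14 and 17 without OA_9570, and 690 and 457 without OA_1038. Leaving out healthy horse ORC_200 gave 203 and 97, ORC_202 gave 690 and 519, ORC_207 gave 146 and 78, and ORC_208 gave 159 and 101. DESeq2 called 935 and 750, weights per library 1370 and 942, and the fit without healthy horses ORC_197 and ORC_202 gave 836 and 558. With the monocyte list mean as a covariate, also chosen after the data were seen, 18 genes of those followed changed direction, among them NLRP3, CTSB and ADAM9, and the lists of B cells (median 0.15, adjusted p = 0.705), resident macrophages (-0.073, 0.778), protease inhibitors (-0.16, 0.778) and T cells (0.12, 0.14) turned and were not called; the monocyte list itself cannot be tested in this fit. Of 49 such genes called in blood, DEGS2, EPS8, GFRA1, LRFN1, PDCD1 and TMEM117 stayed called whichever library was left out, and none changed direction in those fits. The camera call of T cells ended without OA_3850 (adjusted p = 0.13), OA_4110 (0.0524), OA_9570 (0.0785), ORC_202 (0.076), ORC_205 (0.0822) or ORC_209 (0.0606). That of the NF-kappa-B list ended without OA_1038 (0.0686), OA_2615 (0.0536), OA_9350 (0.105), ORC_192 (0.0584), ORC_197 (0.0509), ORC_205 (0.136), ORC_207 (0.0504) or ORC_209 (0.0607). Lipid handling lost it without OA_2615 (0.0716), ORC_188 (0.0511) or ORC_205 (0.0701), and oxidative phosphorylation without ORC_197 (0.0879). The erythroid list lost it without OA_1038 (0.149), OA_2615 (0.0966), OA_3850 (0.0618), ORC_188 (0.0697), ORC_192 (0.055), ORC_197 (0.053), ORC_202 (0.076), ORC_205 (0.0864) or ORC_209 (0.0681).

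The last comparison asked whether OA changed fluid cells and PBMC differently, as the OA effect in fluid minus that in blood. The effect was lower in fluid than in blood for the lists of T cells and of cytotoxic and NK cells, and higher for ribosomal proteins and oxidative phosphorylation. With an estimated correlation none of these 4 was called (adjusted p = 0.309, 0.309, 0.501 and 0.517). Over the 12733 genes tested in both tissues, 2834 differed, 1315 with a higher and 1519 with a lower effect in fluid. The fit with the horse as replicate block called 2895, of which 2223 were shared. Among those with a symbol and a mean of at least 50 in any group, FAM124A had the largest positive difference (6.56, SE 1.61, adjusted p = 0.00526). It was at 4.48 in fluid (limma adjusted p = 0.00788) and -2.08 in blood, which did not pass (0.171). ENPP1, which makes pyrophosphate (5.55), COL14A1 (5.21), MPDZ (5.10) and CHI3L1 (4.99) followed. FOXN1 had the largest negative difference (-4.92, SE 1.49, adjusted p = 0.0188), followed by the kinase TNK1 (-4.64), MCHR1 (-4.36), SLC4A11 (-4.32) and MAP7 (-4.29). All 10 kept their calls in the fit with the replicate block. None of the 10 passed in blood alone, and COL14A1 passed in neither tissue alone (limma adjusted p = 0.0726 in fluid and 0.0671 in blood).

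Camera called 13 of 33 lists in the difference, 12 in the fit with the replicate block (collagens and matrix proteins were lost, adjusted p = 0.136), and 0 with an estimated correlation. Exact permutation of within-horse differences called 8: T cells, cytotoxic and NK cells, MHC class I presentation, checkpoint genes, glycolysis, oxidative phosphorylation, T cell receptor signalling and ribosomal proteins. The median difference was -1.83 for T cells (adjusted p = 0.309 with an estimated correlation), -1.98 for cytotoxic and NK cells (0.309) and 1.14 for ribosomal proteins (0.501), from 0.79 in fluid and -0.36 in blood. Proliferation differed by 0.88 (adjusted p = 0.657 with an estimated correlation), at -0.12 in fluid and -0.98 in blood. With both samples of horse OA_9350 left out the count of genes was 1809, with those of OA_2615 it was 1877, and a fit with the horse as a random block called 3778. FOXN1 lost its call without OA_9350, and CHI3L1 without horse OA_1038 or OA_2615 or healthy horse ORC_197.

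**Figure D3:**
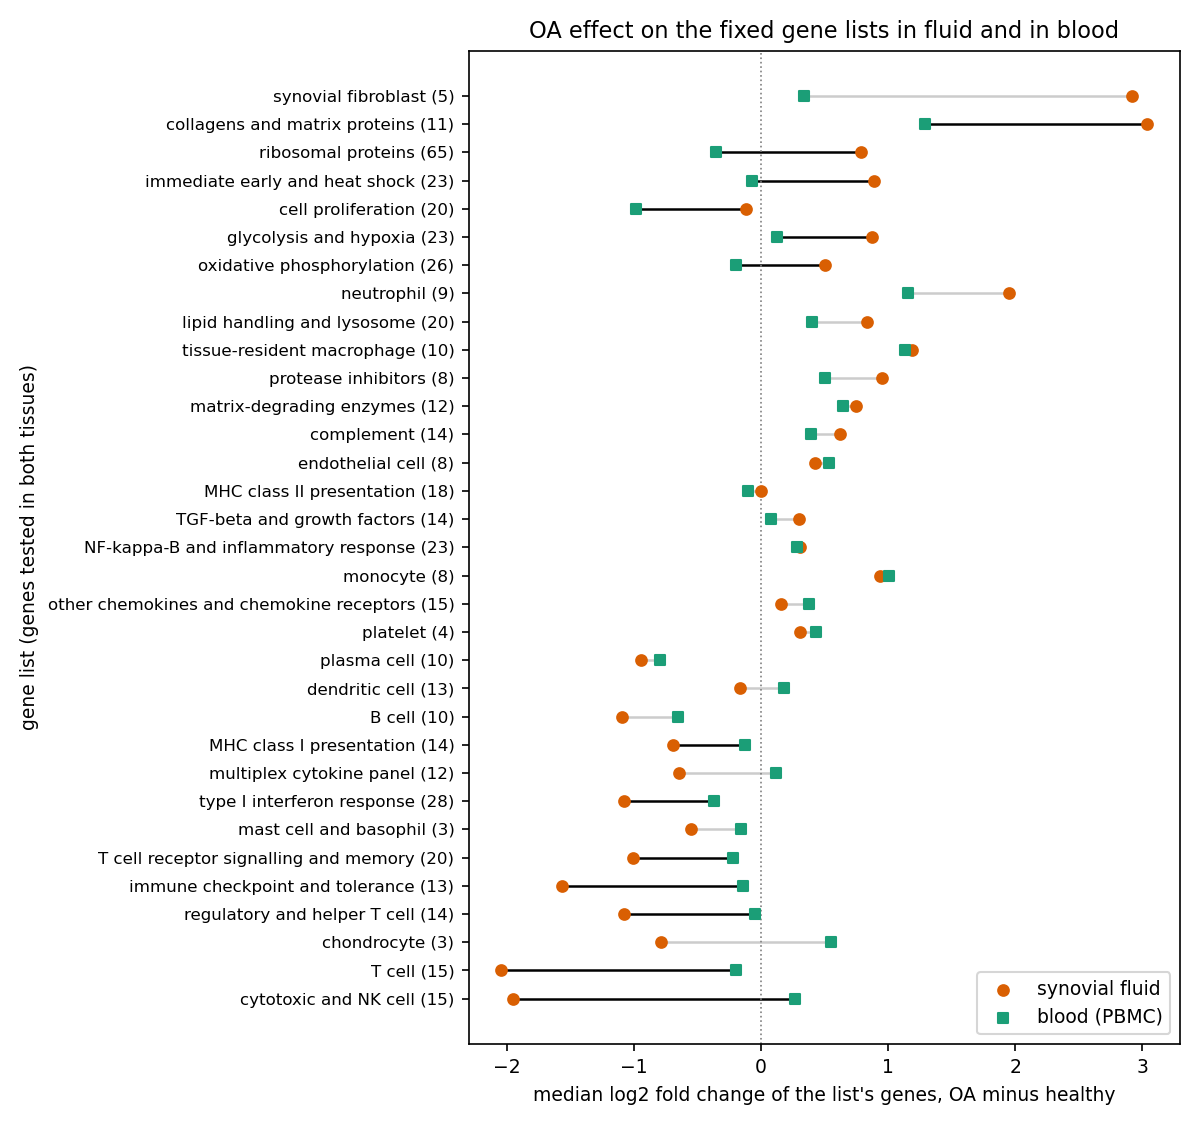
Median log2 fold change (OA minus healthy) of each gene list in fluid (circles) and in blood (squares), with the number of genes tested in both tissues in brackets; black lines join the 13 lists whose difference passed camera and grey lines the others. T cell genes lay at -2.04 in fluid and -0.19 in blood, and ribosomal protein genes at 0.79 and -0.36.

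Of genes tested in both tissues, 126 were higher in OA in both (independent lists would share 54.1) and 84 lower in both (41.4). FN1, THBS1, VCAN, PLAUR, NDRG1 and ADAM9 were among those higher in both, and PDCD1 and USP18 among those lower. Opposite calls numbered 14 for genes higher in fluid and lower in blood (37 for independent lists) and 15 the other way (60.6). The overlaps were not tested, and the horses common to both tissues can add to them. CCR6 was higher in fluid (2.02) and lower in blood (-1.15). Across genes, which are not independent replicates, the fold changes correlated with Pearson's r of 0.281 and Spearman's rho of 0.17. Because the same horses gave both tissues, the disease label was permuted over horses. Of 100 labellings, the real one included, 17 gave as high an r (permutation p = 0.17). The mean of the permutations was 0.206 and the highest 0.452. The covariance was 0.143 against a permuted mean of 0.0398.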

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

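The fits with a T cell or monocyte covariate or thinned reads, the exact permutation of list means, the variance between cell type lists, the match of horse OA_9570 to its own blood, the difference of the proliferation list from lymphocyte lists, every test of lists in the difference between tissues, and the fits without libraries that stand apart were tests chosen only after the results they bear on were seen.

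Of 353 groups of 4 to 10 values, 27 held a sample far from the others (7.65%). Chance flags about 1 in 20 groups of normally distributed values, or 17.6. The 11 healthy fluids exceed this group size and were not screened. Where all other values were 0, as for CCNP, FOXN1 and MZB1 below, any value above 0 is flagged. Healthy blood of horse ORC_209 gave 9 and OA fluid of horse OA_9570 gave 8. As log2 values, horse OA_9570 was low among OA fluids for VAT1L (5.18, others 10.8 to 12.9), HAPLN1 (0, others 7.04 to 9.31), PDPN (0, others 7.05 to 8.92), COL11A1 (0, others 6.33 to 8.61), the collagen list mean (6.31, others 11.6 to 13.4) and the synovial fibroblast list mean (5.27, others 11.1 to 13). It was high for IRF9 (11.9, others 10.8 to 11.1) and CCNP (4.61, others 0). The fluid of OA_2615 was low for UQCRC2 (11.5, others 11.6 to 11.7) and for the T cell receptor signalling list mean (9.18, others 10.4 to 10.7), and the fluid of OA_3850 was high for FOXN1 (4.99, others 0) and MZB1 (1.64, others 0). The blood of OA_9350 was low for CCR7 (10.6, others 11.8 to 12.4). Healthy blood ORC_209 was low for PLAUR (6.96), IL10RA (11.5), NLRP3 (9.75), NDRG1 (8.46), LAMP1 (13) and TIMP2 (9.99), and the means of monocytes (11, others 11.7 to 12.1), resident macrophages (6.84) and protease inhibitors (8.59). Healthy blood ORC_202 was low for SALL3 (0, others 4.13 to 6.12) and BLK (10, others 11.1 to 12.1) and high for IL1B (9.72, others 5.81 to 7.5). Healthy blood ORC_188 was low for CCR6 (8.45, others 9.25 to 9.97), and healthy blood ORC_197 high for SERPINB1 (13.1, others 12.2 to 12.6).

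The OA effect differed between fluid and blood, by the test of the difference, for 2834 genes (1809 without both samples of horse OA_9350 and 1877 without those of OA_2615). The named ones were FAM124A (6.56), ENPP1 (5.55), COL14A1 (5.21), MPDZ (5.10), CHI3L1 (4.99), MAP7 (-4.29), SLC4A11 (-4.32), MCHR1 (-4.36), TNK1 (-4.64) and FOXN1 (-4.92). The 13 lists, with an adjusted p of 0.099 to 0.657 with an estimated correlation, had median differences of 1.14 (ribosomal proteins), -1.83 (T cells), -1.98 (cytotoxic and NK cells), 0.594 (oxidative phosphorylation), 0.797 (glycolysis and hypoxia), 0.889 (immediate early and heat shock), 0.878 (proliferation), -0.864 (T cell receptor signalling), -0.655 (interferon response), -1.01 (checkpoint), -1.12 (regulatory and helper T cells), -0.547 (MHC class I presentation) and 1.80 (collagens and matrix proteins).

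Chance is an unlikely source of the gene counts, though 100 splits cannot exclude it. The real split gave 3899 called genes in fluid (highest of the other splits 338), 706 in blood (1) and 2834 for the difference (1). Each was reached by 1 of 100 splits, the real one. The blood count also rested on single horses, with 31 genes called without OA_9570, 33 without OA_3850 and 35 without OA_9350. The count of 17 lists called in blood passed the bound written beforehand, with 4 of 100 splits as large, the real one included. Other splits called up to 18. That bears on the count alone: an estimated correlation called 0 of these lists and exact permutation 9, so chance is not excluded for each list. Nor can chance be excluded for the 17 lists called by camera in fluid, since 13 of 100 splits gave as many (highest other 23). The same holds for the 13 lists of the difference, since 21 of 100 did (highest other 17). A sequencing batch that follows disease moves with the real split, so these splits leave it open in both tissues.

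Interferon genes fell together with T cell genes in OA fluid. With the T cell list mean as a covariate the interferon median was -1.05 (-1.21 to -0.935 with each library left out), against -1.08 without it. This median lay past the bound written beforehand against fewer T cells as the whole source, in a fit chosen after the fall was seen. The list mean kept a 95% interval of -1.96 to -0.203 (-1.59 to -0.647 without the covariate), wide enough to leave part of the fall open. A stricter reading, in which the interval must also exclude a small fall, would leave it undecided. T cell means also nearly separate the disease groups, with ORC_202 alone of the healthy fluids inside the OA range. The adjusted value thus rests on little overlap, so this fit cannot decide the question, and fewer T cells as the whole source is not excluded. No single library explained the interferon fall, since the highest median with 1 library left out was -0.94. A lower T cell share that raises every other cell type alike was first tested as B cell minus monocyte list means (-1.96, exact permutation p = 0.0971), which did not decide it. The test that replaced it after that result was the variance of the OA effect over 11 cell type lists. These left out the T cell, the cytotoxic and NK cell and the regulatory and helper T cell lists. The variance exceeded that of other splits (1.74 against a median of 0.426, exact permutation p = 0.0295). Within the 11 lists the effects ran from B cells at -1.03 to synovial fibroblasts at 3.14. Unequal changes of these lists can come from a shift in cell types or from changed expression within cells, which marker lists cannot separate. They do not decide whether the interferon response was lower within cells. A lower interferon response in the OA joint stays a hypothesis, which expression in sorted cells of the same fluids would decide. Dilution by cell types whose lists rose, and a change within them, stay open.

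Proliferation genes fell in OA blood, whose libraries were also deeper. With reads thinned to equal totals the median was -0.989 (-1.14 to -0.816 with each library left out), which argues against depth. With the monocyte list mean as a covariate it was -0.695 (-1.05 to -0.36), and the list mean went from -0.957 (SE 0.283) to -0.786 (SE 0.473), with a 95% interval of -1.82 to 0.246. A higher monocyte share that dilutes every lymphocyte alike, as the whole source, would lower proliferation no more than the lymphocyte lists. Proliferation fell more than the T cell list (difference of means -0.77, exact permutation p = 0.0396). It also fell more than the cytotoxic and NK cell list (-1.22, p = 0.0044, and 0.011 or less with each library left out). Proliferation did not pass as falling more than the B cell list (-0.238, p = 0.461; -0.468 to -0.0833 with each library left out). For T cells p was 0.0529 to 0.0934 without OA_1038, OA_3850, OA_4110, OA_9350, ORC_188, ORC_192, ORC_197, ORC_200, ORC_207 or ORC_208, while the difference stayed between -0.928 and -0.638. The T cell comparison thus did not hold at p below 0.05 with each library left out. Only the comparison with the cytotoxic and NK cell list held throughout against such dilution as the whole source. The answer differed between lymphocyte lists, so such dilution is not excluded. Dilution of part of the lymphocytes and a lower rate of division cannot be told apart here, because monocyte means separate the disease groups and B cell markers changed as well (median -0.812).

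The fluid of horse OA_9570 lay apart from the other OA fluids. A fluid sample of another horse is argued against by its correlation with its own blood over horse marker genes, 0.626, against 0.222 for the highest other horse. Of the genes lower in the other 4 OA fluids, 81.4% lay below the healthy median in OA_9570, and of the genes higher in them 61.7% lay above it (31.7% to 70.2% in healthy fluids, 4 of which reached 70% or more). Taken by the bound written beforehand this counts as a fluid without those OA differences, because healthy horse ORC_202 reached 86.5%; it was left open since the other 10 healthy fluids reached 16.4% to 70.5%, a reading made after the value was seen. Whether OA_9570 shares the OA state of the other 4 cannot be told apart from a different cell mixture in this fluid, and no biological explanation was tested.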

How the results depend on the processing

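Fits with a covariate, thinned reads, exact permutation of list means, or without libraries that stand apart were tests chosen only after the results were seen, as was every test of lists in the difference between tissues; the others were planned. Reads thinned to the smallest total of each tissue gave 1997 higher and 1882 lower genes in fluid and 399 and 273 in blood. The counts thus depended little on unequal depth, and whether deeper libraries would change them was not tested. The number of horses limits the precision.

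In fluid, leaving out each library gave 1208 (without OA_2615) to 2575 (without OA_9570) genes higher, with 1288 without OA_3850, 1298 to 2168 lower and 16 to 19 lists. Of 99 called genes named by the rule 77 stayed called with each library left out and none reversed in those fits. Equal totals gave 1302 higher, weights per library 3654 higher and 2981 lower; for equal totals the shift of the median to -0.12 is part of the scaling, and for weights the cause was not tested. With the T cell covariate limma called 0 genes higher and 0 lower (1663 at an unadjusted p under 0.05; no other tool was run with it). The median SE was 0.498 (0.299 without it), the fold changes correlated with the main ones at 0.57, and 9 lists were called. With it these genes reversed: PDCD1 0.14, CCL5 0.60, ADAM9 -0.53, CD36 -0.027, MAP6 1.47, TIMP2 -0.36, PPARG -0.21, HAS1 -0.39, TGFBI -0.75, STAB1 -0.56, MERTK -0.36, RECK -0.28 and COL11A1 -1.37. So did the lists of matrix-degrading enzymes (-0.27), lipid handling (-0.71, called lower, adjusted p = 0.00632), protease inhibitors (-0.29) and resident macrophages (-0.79); the cause was not tested. An estimated correlation called 0 lists by camera (6 at an unadjusted p under 0.05; 16 by fry).

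In blood, leaving out each library gave 14 (without OA_9570) to 690 (without horse OA_1038 or healthy horse ORC_202) genes higher, 17 to 519 lower and 13 to 18 lists; 16 and 17 genes without OA_3850, 17 and 18 without OA_9350, 203 and 97 without healthy ORC_200, 146 and 78 without ORC_207, 159 and 101 without ORC_208, and 457 lower without OA_1038. Without OA_9570, 2442 genes were at an unadjusted p under 0.05 (3273 with it), and the fold changes correlated with the main ones at 0.981. DESeq2 gave 935 and 750, weights per library 1370 and 942, and leaving out healthy ORC_197 and ORC_202 gave 836 and 558; the cause was not tested. Lists numbered 0 with an estimated correlation (4 at an unadjusted p under 0.05), 10 with fry, 9 with exact permutation and 8 with the monocyte covariate. That covariate left 0 genes higher and 0 lower by limma (439 at an unadjusted p under 0.05; no other tool was run with it). With it these reversed: ADAM9 -0.0074, NLRP3 -0.073, CTSB -0.072, TGFBI -0.14, ENTPD1 -0.032, NDRG1 -0.014, HK1 -0.012, CD14 -0.29, VSIR -0.11, LAMP1 -0.18, TIMP2 -0.35, CD163 -0.32, CTSS -0.16, TREM1 -0.38, IL18 -0.30, SIGLEC1 -0.097, C1QB -0.048 and CD247 0.020, and the lists of monocytes (-0.18), B cells (0.15), resident macrophages (-0.073), protease inhibitors (-0.16) and T cells (0.12). For the monocyte list this fit is no test, as the covariate is its own mean.

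For the difference between tissues, leaving out each horse, with both of its samples where it gave both, gave 1809 (without OA_9350) to 3207 (without ORC_202) genes. The replicate block, on within-horse differences of 5 OA and 8 healthy horses, gave 2895 genes and 12 lists; exact permutation of list means in these pairs gave 8 lists, and an estimated correlation 0. The block ended the call of collagens and matrix proteins and changed no other call named. The correlation of fold changes was 0.25 with the replicate block and 0.222 to 0.337 with each horse left out.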

Other observations

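The exact permutation tests given here were chosen only after the results were seen; the gene tests were planned. In OA fluid, of 7 tested chondrocyte markers, ACAN, the core protein of aggrecan, rose by 5.26 (SE 1.19, limma adjusted p = 0.00509), HAPLN1, which links aggrecan to hyaluronan, by 4.26 and COMP by 1.74. The list was not called by camera (adjusted p = 0.175, and 0.586 with an estimated correlation) and passed exact permutation (adjusted p = 0.0449). Its mean was 2.16 in horse OA_9570, below every healthy fluid (2.51 to 5.43), and 6.62 to 7.81 in the other OA fluids. The synovial fibroblast list also set OA_9570 apart from the other OA fluids (5.27, others 11.1 to 13), but there it lay within the range of the healthy fluids. COL2A1, the main collagen of cartilage, was at -1.37 (adjusted p = 0.13). HAPLN1 was at 0 in horse OA_9570 and lost its call with edgeR (adjusted p = 0.0676), and COMP lost its call with equal totals (adjusted p = 0.0804). Growth factor genes moved both ways in fluid (camera adjusted p = 0.246): VEGFA rose from 231.7 to 1857, TGFB2 by 2.85 and TGFBI by 1.24, and SMAD3 changed by -1.25. TGFB2 and TGFBI lost their calls with equal totals (adjusted p = 0.0529 and 0.079). Of the plasma cell markers in fluid IRF4 (-1.01), PRDM1 (-0.87) and MZB1 (-3.82) fell. Their list was not called by camera (adjusted p = 0.175, and 0.406 with an estimated correlation) but passed exact permutation (adjusted p = 0.034).

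In blood the growth factors HGF (1.33, SE 0.27), IGF2 (1.30) and TGFBI (0.88) rose in OA, in a list that camera did not call (adjusted p = 0.454). Glycolysis and hypoxia genes were not called as a list (camera adjusted p = 0.137), and 4 rose: HK2 (0.97), EGLN3 (0.82), NDRG1 (0.79) and HK1 (0.39). Of the checkpoint list (camera adjusted p = 0.454) ENTPD1, which breaks down extracellular ATP, rose by 0.87 and IL10RA by 0.54, and PDCD1 fell by 0.69. Each of these 9 genes that rose lost its call when some single libraries were left out.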
